A study of Mus musculus with 6 samples.

How the data were processed

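RNA-seq was measured in 6 libraries of mouse alveolar macrophages, the resident phagocytes of the lung air spaces, from C57BL/6 animals after an exposure that the labels abbreviate as BLM. Per the labels, 3 samples came from wild-type mice and 3 from A20 conditional knockout mice. A20 is the ubiquitin-editing protein encoded by Tnfaip3, an inhibitor of NF-kB signalling. The labels do not give the Cre driver, the deleted exons, the dose or the day of collection. Per the labels' protocols, cells were flash frozen, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with the KAPA Stranded RNA-Seq kit. No sort or marker used to isolate the cells is given. The labels do not say whether each replicate was a single animal or a pool, so p-values measure the spread between these samples, part of which may be technical.

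The deposited table gives FPKM, a count of fragments scaled to transcript length and to the mapped fragments of the library, for each gene and library, per the file headers. The genome build was GRCm38, per the submitters' processing notes. The aligner, the quantifier, the use of strand and the annotation release are not given in the sources used here. The table lists 11789 genes, all of protein-coding type. Each had a mean FPKM of at least 0.5001 in its higher group, so genes below this level in both groups were not analysed here. Of the listed gene IDs, 11771 were found in GENCODE M21, and 10750 had the same coordinates there. Sums of FPKM ran from 266094 to 294525 per library. The low values showed no steps from which whole reads could be recovered, so the read depth of each library is unknown and no counting interval is given. There are 8 symbols carried by 2 gene IDs each. Both IDs were kept as separate genes and count as 2 members of a gene list, which holds for 1 symbol of the list of recruited macrophage genes.

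Table columns were assigned to groups by name. The 3 columns named for A20 (A20-1, A20-3 and A20-4) were taken as the knockout samples. The 3 columns named only for the exposure (BLM1, BLM2 and BLM3) were taken as the wild-type samples, since the labels hold only these 2 groups. The numbers in the column names are not the replicate numbers of the sample titles, so columns stand for a group and not for a single titled sample. All per-sample columns were used. No 2 libraries held the same values.

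Genes with a mean FPKM of at least 1 over the 6 libraries were tested (10696 genes, 1093 left out). Values were transformed to log2(FPKM + 1), a pseudocount of 1, and compared with limma 3.58.1 in R (lmFit, then eBayes with a trend on mean expression), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are given as knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. A gene past the threshold is said to have risen or fallen. For Tnfaip3 an exact two-sided permutation test of the FPKM values was added, which cannot go below 0.1 with 3 libraries against 3. Whole-gene FPKM counts every exon, so a transcript that keeps most exons after a conditional deletion would still be measured.

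Gene lists numbered 34 of pathways, cell types and RNA quality, of which 33 had at least 4 genes tested. The list of eosinophil and mast cell genes had 0 of its 10 genes in the table and was not tested. Lists were tested with camera (preset correlation of 0.01 between genes), which asks whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with the correlation estimated from the data, and fry, which asks only whether the genes of a list move one way. The estimated form of camera also uses only the residual degrees of freedom of these few libraries. A call lost with it need not mean that the genes of a list are correlated. Counts of genes past the threshold are given over all genes tested and adjusted over the list alone. The groups, tests, lists and rule for named genes were fixed before the data were examined. The named genes are Tnfaip3, the 14 largest rises and the 14 largest falls among genes past the threshold whose 3 values in one group all lay outside the 3 of the other (predicted, clone, mitochondrial and receptor segment names left out), the 3 genes with the smallest p in each list described singly, and 14 fixed genes of macrophage activation. Il6, one of these, was not analysed here, and Il10 was below the minimum mean FPKM. Which lists are described by single members was chosen after values were seen. The other 12 lists are given as lists only, among them erythroid cells and fibroblasts and endothelium, some of whose members turned direction under an alternative. Other genes are marked as chosen after their values were seen. Some genes that this rule or a list count includes are not reported here by name.

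The fit was tested on simulated values for the same 10696 genes, with their means and residual spread and 200 genes changed. It called 62 of 100 genes changed by 1 log2 unit, 87 of 100 changed by 2, and 6 unchanged genes, with 0 wrong signs. The simulated noise was independent between genes and between libraries, and no library was set apart. These rates check the fit and may not hold for the real values, where genes move together and BLM3 stands apart. Alternatives were a pseudocount of 0.1 or 5, no filter or a minimum mean FPKM of 5, rescaling to a fixed sum per library (TPM, with pseudocount and minimum scaled alike), median-ratio scaling, quantile normalization, limma without trend, with robust eBayes or with array weights, other thresholds, and leaving out each library. The removal from each library of a smooth trend on GC content and transcript length was added after seeing the data.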

Results

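The series measured gene expression in alveolar macrophages from mice exposed to BLM, in 3 libraries labelled wild type (BLM1, BLM2 and BLM3) and 3 labelled A20 conditional knockout (A20-1, A20-3 and A20-4). The comparison asks how macrophages from mice labelled A20 conditional knockout differ from those of wild-type mice after the exposure. The labels do not say in which cells A20 was deleted. The read depth behind the FPKM values is unknown. The knockout libraries resembled each other closely, with Pearson correlations across genes of 0.977 to 0.980, and BLM1 and BLM2 correlated at 0.982. Library BLM3 correlated with these 2 at only 0.925 and 0.913, and the first principal component, which held 56.6% of the variance, set it apart from the other 5 libraries. Genes are not independent replicates, so these correlations describe the libraries only. Values without BLM3 are given for each list whose call it changed.

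Tnfaip3 (ENSMUSG00000019850.11, GRCm38 chromosome 10, 19000910 to 19015657, minus strand), the targeted gene, showed no detectable fall in the libraries labelled knockout. Its FPKM was 8.44, 12.9 and 6.80 in A20-1, A20-3 and A20-4, and 4.47, 2.18 and 21.6 in BLM1, BLM2 and BLM3. The means were 9.39 ± 3.18 (SD, n = 3) in the knockout and 9.42 ± 10.6 (SD, n = 3) in the wild-type libraries. The log2 difference was 0.46 ± 0.69 (SE) with a limma adjusted p of 0.734, and the exact two-sided permutation test gave p = 1, where 0.1 is the smallest value it allows. Without BLM3 the difference was 1.27 ± 0.31 (SE, adjusted p = 0.0797), and without BLM2 it was -0.14 (adjusted p = 0.913). The gene's own level thus gives no support to the knockout label. It cannot check the deletion either way, because the deleted exons are not given and FPKM covers the whole gene. Every direction below is therefore one between libraries as labelled.

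Of 10696 genes tested, 91 fell and 27 rose in the knockout libraries (limma, adjusted p under 0.05). The most marked fall was in Npy, which encodes neuropeptide Y, from an FPKM of 33.6 ± 9.69 in wild type to 2.78 ± 0.524 in the knockout libraries (SD, n = 3 each), a log2 difference of -3.16 ± 0.24 (SE, limma adjusted p = 0.00889). The fatty acid binding protein gene Fabp7 followed with -2.31 ± 0.14 (SE), and the serotonin receptor gene Htr2b with -2.23 ± 0.18. Mfge8, whose product bridges apoptotic cells to phagocytes, went from 188 ± 32.4 to 42.2 ± 12.9 FPKM, and Mmp12, macrophage elastase, from 83.4 ± 13.9 to 18.0 ± 2.82 (SD, n = 3). Other named falls were in the complement receptor C3ar1, the tight junction gene Cldn4, the retinol dehydrogenase Dhrs9, the metalloprotease Adam8, the prolyl isomerase Fkbp11, the complement chain C1qb, the chemokine Ccl9 and the amino acid transporter Slc36a2. These had log2 differences between -2.14 for C3ar1 and -1.92 for Slc36a2. With a pseudocount of 5, Cldn4, Dhrs9 and Slc36a2 were not called (limma adjusted p = 0.0563, 0.0577 and 0.0577).

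All 118 called genes had non-overlapping values in the 2 groups, as did 29.0% of all genes tested. Chance alone gives 10% for 3 against 3 on average over the possible splits. Genes are not independent, so a single split can lie far from this, and the difference was not tested. The calls depended on single libraries. A fit without a library also has fewer values, so a lost call need not mean a smaller difference. The log2 difference ran from -3.42 to -3.01 for Npy, the most marked called fall, and from 2.12 to 2.42 for Tppp, the largest named rise. Without A20-3, limma called 0 genes (1694 at an unadjusted p under 0.05), without A20-4 0 rises and 14 falls, without BLM1 0 rises and 4 falls, without A20-1 11 rises and 24 falls, and without BLM2 16 rises and 76 falls. Without BLM3 there were 144 rises and 267 falls, which included the 27 rises and the 91 falls of the 6 libraries. Rescaling to TPM moved the split to 49 rises and 69 falls, or 41.5% rises against 22.9% as deposited. No named gene called here changed sign when any library was left out. This had to follow, because their values did not overlap between the groups, so it is no further support.

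**Figure D1:**
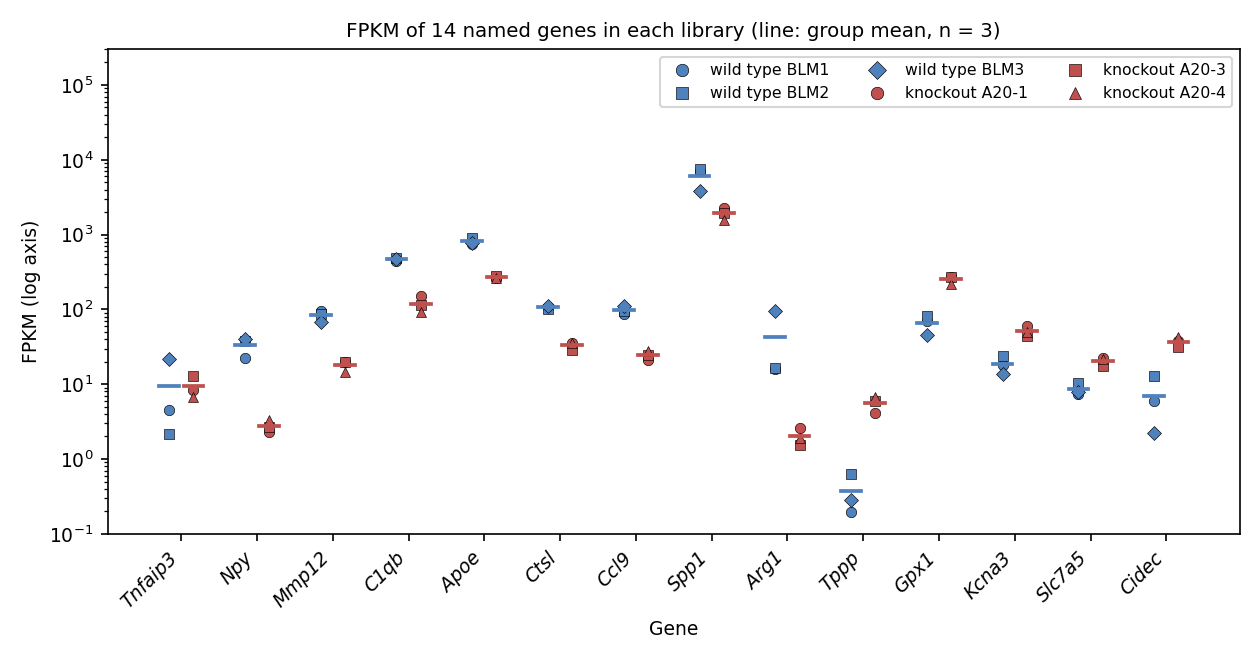
FPKM, on a log axis, of 14 named genes in each library; symbols are single libraries labelled wild type (blue) or knockout (red), and horizontal lines are group means (n = 3). Apoe lies between 750.4 and 908.3 in the wild-type libraries and between 265.5 and 279.8 in the knockout libraries, while Tnfaip3 overlaps between the groups.

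Of 15 tested genes that mark the lipid-laden macrophages of scarred tissue, 6 fell and 0 rose, or 12 fell when adjusted over the list alone, and 14 of 15 had a negative difference. Without BLM3, 11 fell over all genes. The cathepsin gene Ctsl went from an FPKM of 107 ± 5.42 in wild type to 33.2 ± 4.22 in the knockout libraries (SD, n = 3 each), and Apoe, the lipoprotein component apolipoprotein E, from 812 ± 84.6 to 270.4 ± 8.17. Syngr1 fell by 0.93 on the log2 scale, from 15.1 ± 0.689 to 7.42 ± 0.591 FPKM. The median log2 difference of the list was -0.85, with a camera adjusted p of 3.62e-12, and it was -0.84 without BLM3. With an estimated correlation its adjusted p was 0.121, and fry gave an adjusted p of 0.00239. That adjusted p of 0.121 is the smallest of any list. Thus 0 of the 19 list calls made with the preset correlation held with an estimated one. Correlated genes were not the reason for every loss. The estimate was -0.019 for alternative activation, 0.0016 for profibrotic mediators and 0.0090 for NRF2 and oxidative stress, below the preset 0.01. It was higher for the other called lists, up to 0.93 for mitochondrially encoded transcripts.

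Of 21 tested profibrotic mediators and matrix remodelling genes, 3 fell and 0 rose, or 9 fell and 1 rose when adjusted over the list alone, and 15 had a negative and 6 a positive difference. The 3 were Mmp12, the urokinase gene Plau, at 43.2 ± 7.83 FPKM in wild type and 12.0 ± 2.98 in the knockout libraries (SD, n = 3), and the collagenase gene Mmp13, at 2.06 ± 0.70 and 0.178 ± 0.105, which was not called with a pseudocount of 5 (limma adjusted p = 0.0577). Without BLM3, 8 fell over all genes. Tgfb1, which encodes transforming growth factor beta 1, had 64.8 ± 6.33 and 67.1 ± 2.37 FPKM (log2 difference 0.05 ± 0.11, SE, limma adjusted p = 0.805). Spp1, osteopontin, had 6150 ± 1981 FPKM in wild type and 1919 ± 359 in the knockout libraries (SD, n = 3), a log2 difference of -1.64 ± 0.29 (SE) that missed the threshold with 6 libraries (limma adjusted p = 0.0616) and passed it without BLM3 (-1.94, adjusted p = 0.0147). The list had a median of -0.92 (camera adjusted p = 3.44e-05), or -0.71 without BLM3. Its adjusted p was 0.121 with an estimated correlation and 0.0132 with fry.

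The list of monocyte and recruited macrophage genes had a median log2 difference of -1.29, and 4 of 19 tested members fell with 0 rises (9 falls and 1 rise adjusted over the list alone). All 3 chains of complement C1q were among them. C1qa went from 426 ± 12.3 to 116.6 ± 27.8 FPKM, C1qb from 468 ± 21.9 to 119.3 ± 28.6, and C1qc from 195 ± 10.2 to 56.2 ± 11.9 (SD, n = 3 each). Camera gave an adjusted p of 4.39e-05, the estimated correlation an adjusted p of 0.588, and fry 0.105. Library BLM3 carried part of this difference, since the list's median lay 0.93 log2 units above BLM1 and BLM2 there, and without it the list's median was -0.70 (camera adjusted p = 0.00149, adjusted p = 0.342 with an estimated correlation). Without BLM3 the recruited list had 1 rise and 4 falls over all genes. The dendritic cell list had -0.74 without BLM3.

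Alveolar macrophage identity genes, by contrast, had a median of 0.62 (camera adjusted p = 0.0209; adjusted p = 0.806 with an estimated correlation). Of 22 tested, 1 fell and 0 rose over all genes, and 5 rose and 1 fell when adjusted over the list alone. Without BLM3, 5 rose and 2 fell over all genes, and 10 rose and 4 fell adjusted over the list alone. The member that fell was Marco, a scavenger receptor, from 32.2 ± 5.66 to 8.43 ± 3.57 FPKM (SD, n = 3). The call of Marco ended without any single library other than BLM3 (limma adjusted p 0.0765 to 0.148), with a pseudocount of 0.1 (0.0511), under TPM (0.0512), with quantile normalization (0.0521) and with the GC and length trend removed (0.0602). The lipid droplet gene Cidec had 6.99 ± 5.31 FPKM in wild type and 36.9 ± 5.58 in the knockout libraries (limma adjusted p = 0.0747), and the keratin gene Krt79 4.50 ± 3.997 and 29.3 ± 10.4 (adjusted p = 0.0889). Both passed without BLM3, with adjusted p of 0.0266 and 0.0462. The list's call was lost without BLM3 (median 0.27, adjusted p = 0.119), without A20-1 (adjusted p = 0.0976) and without A20-4 (adjusted p = 0.0630), under TPM (adjusted p = 0.05425) and with array weights (0.0642). BLM3 lay 0.99 log2 units below BLM1 and BLM2 on this list (median -0.99).

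Lipid handling and scavenger receptor genes overlapped with these groups. In the list of lipid uptake, storage and efflux, 2 of 18 genes fell and 0 rose (3 falls adjusted over the list alone). They were Fabp5, a fatty acid binding protein also in the scar-associated list, at 217.1 ± 10.4 and 125.6 ± 1.14 FPKM, and the scavenger receptor Cd36 at 92.5 ± 12.5 and 30.7 ± 8.85 (SD, n = 3). The median was -0.43 (camera adjusted p = 0.0209, adjusted p = 0.626 with an estimated correlation), and the call was lost without A20-3 (adjusted p = 0.0765), BLM1 (0.0575) or BLM2 (0.129). Pltp, the phospholipid transfer protein gene, had 75.6 and 47.4 FPKM and was not called (limma adjusted p = 0.118). Of 23 phagocytic and pattern recognition receptor genes, 3 fell, namely Cd36, Marco and the scavenger receptor Msr1 (46.0 ± 5.35 to 19.7 ± 4.61 FPKM), with 0 rises and 4 falls adjusted over the list alone, and 5 fell without BLM3. With the GC and length trend removed, Cd36 was not called (limma adjusted p = 0.0527), nor was Marco. That list was not called as a whole (median -0.15, camera adjusted p = 0.0578), but was called without A20-1 (median -0.48, adjusted p = 0.0195), without BLM1 (-0.39, 0.0280) and under TPM (-0.09, 0.0265). With an estimated correlation the adjusted p was 0.588 with 6 libraries and 0.410, 0.539 and 0.592 in these 3 settings, and without BLM3 the median was -0.06.

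Among 17 genes of alternative activation, 1 fell and 0 rose, namely Msr1, and 4 fell adjusted over the list alone. Without BLM3, 6 fell over all genes and 8 adjusted over the list alone. Arg1, the arginase typical of alternatively activated mouse macrophages, had FPKM of 15.9, 16.5 and 94.1 in BLM1, BLM2 and BLM3 and a mean of 2.02 ± 0.523 (SD, n = 3) in the knockout libraries. Its log2 difference of -3.35 ± 0.66 (SE) missed the threshold (limma adjusted p = 0.0747) and passed it without BLM3 (-2.53, adjusted p = 0.00647). The scavenger receptor gene Stab1 had 6.44 ± 3.75 and 1.98 ± 0.312 FPKM (adjusted p = 0.120, or 0.0322 without BLM3). Other markers of this state were not called. Chil3 had 3873 ± 883 FPKM in wild type and 4364 ± 1101 in the knockout libraries (adjusted p = 0.743), Mrc1 149.1 ± 68.9 and 236 ± 27.0 (adjusted p = 0.295), and Retnla 2.50 ± 1.51 and 0.975 ± 0.349 (adjusted p = 0.232). Il10 was untested, at 3.43 FPKM in BLM3 and at most 0.234 in the other libraries. The list had a median of -0.51 (camera adjusted p = 0.0256, adjusted p = 0.460 with an estimated correlation), or -0.22 without BLM3 (camera adjusted p = 0.000365, adjusted p = 0.377 with an estimated correlation), and its call was lost without A20-3 (adjusted p = 0.0765) or BLM2 (0.124, median -0.12), with a minimum mean FPKM of 5 (0.164) and with quantile normalization (0.0591).

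The median of 21 cytokine and chemokine genes was -1.23 with 6 libraries (camera adjusted p = 0.00544, adjusted p = 0.626 with an estimated correlation) and -0.05 without BLM3 (adjusted p = 0.0815) or -1.86 without BLM1 (4.71e-05, adjusted p = 0.542 with an estimated correlation) and -0.10 with array weights (0.180), and in BLM3 it lay 2.67 log2 units above BLM1 and BLM2. Only Ccl9, from 97.5 ± 12.1 to 24.5 ± 3.57 FPKM (SD, n = 3), was called over all genes, and 3 fell adjusted over the list alone. Without BLM3, 2 fell and 0 rose over all genes, namely Ccl9 and Il1a (-0.82, limma adjusted p = 0.0482), of which Il1a was chosen after its values were seen, and 8 fell and 1 rose adjusted over the list alone. Without BLM3 the log2 difference was -1.69 for Ccl2, -1.51 for Ccl12, -1.16 for Tnf and 1.92 for Il1b, with adjusted p of 0.0585, 0.0581, 0.0947 and 0.0588. The chemokine Cxcl16 had 49.2 ± 5.33 and 29.5 ± 4.39 FPKM (limma adjusted p = 0.0747), and Ccl12 8.81 ± 6.93 and 1.01 ± 0.383 (adjusted p = 0.109). Tnf was at 12.4, 8.47 and 75.2 FPKM in BLM1, BLM2 and BLM3 against a knockout mean of 4.26 ± 1.70 (adjusted p = 0.202). Il1b was at 13.2, 23.1 and 491 against 74.1 ± 30.4 (adjusted p = 0.899), and Ccl2 at 3.99, 9.63 and 56.3 against 1.32 ± 0.632 (adjusted p = 0.155). Cxcl10 reached 36.1 FPKM in BLM3 against 1.90 and 3.05 in BLM1 and BLM2 and 2.41 ± 1.12 in the knockout libraries (adjusted p = 0.495), and Nos2 reached 12.0 in BLM3 and at most 0.121 elsewhere (adjusted p = 0.513).

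The NF-kB feedback and target genes, which A20 restrains in its textbook role, had a negative median in the libraries labelled knockout. Of 22 tested, 0 were called in either direction, over all genes or adjusted over the list alone, and the median was -0.46 (camera adjusted p = 0.00485, adjusted p = 0.728 with an estimated correlation), or -0.06 without BLM3 (adjusted p = 0.310), and its call was lost with array weights too (0.0958). Without BLM3 1 member rose, Tnfaip2 (log2 difference 0.79, limma adjusted p = 0.0276), which had 0.58 with 6 libraries (adjusted p = 0.179) and was chosen after its values were seen. The smallest p belonged to the survival gene Bcl2a1b, at 224 ± 26.5 FPKM in wild type and 161 ± 7.44 in the knockout libraries (SD, n = 3, limma adjusted p = 0.118), the subunit Relb (14.4 ± 3.53 and 9.09 ± 0.323, adjusted p = 0.145) and Cd40 (2.18 ± 0.729 and 0.943 ± 0.303, adjusted p = 0.154). Bcl2a1b has close paralogs, so its value is uncertain where reads could be split. The A20 partners and other genes of linear or K63 ubiquitin signalling had 0 of 19 called, a median of 0.02, a mean of -0.04 and a camera adjusted p of 0.490. Otulin, Rnf11 and Cyld had the smallest p there, with limma adjusted p of 0.139, 0.159 and 0.338 and log2 differences of -0.40, -0.40 and 0.31.

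Interferon-stimulated genes had a median log2 difference of -0.85 over 30 genes (camera adjusted p = 9.62e-06, adjusted p = 0.685 with an estimated correlation, fry adjusted p = 0.460), with 0 genes called over all genes or adjusted over the list alone. Without BLM3, in which the list's median lay 1.76 log2 units above BLM1 and BLM2, it was -0.38 (camera adjusted p = 0.00201, adjusted p = 0.708 with an estimated correlation). Mx1, an antiviral GTPase, had 10.7 ± 4.32 FPKM in wild type and 3.52 ± 1.00 in the knockout libraries (SD, n = 3, limma adjusted p = 0.0857), Oas1a 42.7 ± 15.2 and 22.4 ± 1.34 (adjusted p = 0.125), and Bst2 110.6 ± 43.5 and 62.5 ± 7.21 (adjusted p = 0.193). Mx1 and Oas1a passed without BLM3, both with an adjusted p of 0.0482. The neutrophil list had a median of -1.35 with 6 libraries and 0.18 without BLM3, and it was called in neither (camera adjusted p = 0.304 and 0.826, 1 rise over all genes and adjusted over the list alone, and 2 rises and 1 fall over all genes without BLM3), although it was without BLM1 (median -1.90, adjusted p = 0.0323, adjusted p = 0.731 with an estimated correlation). Without BLM2 its median was -2.03 (adjusted p = 0.137), and with array weights -0.01 (0.645). S100a8 had 82.6, 78.0 and 861 FPKM in BLM1, BLM2 and BLM3 and 33.5 ± 5.97 (SD, n = 3) in the knockout libraries (adjusted p = 0.208, or 0.0185 without BLM3 with a log2 difference of -1.25), and the chemokine receptor Cxcr2 8.70, 5.66 and 52.6 against 4.41 ± 0.869 (adjusted p = 0.303). Fpr1, the formyl peptide receptor, is the member of this list that rose.

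**Figure D2:**
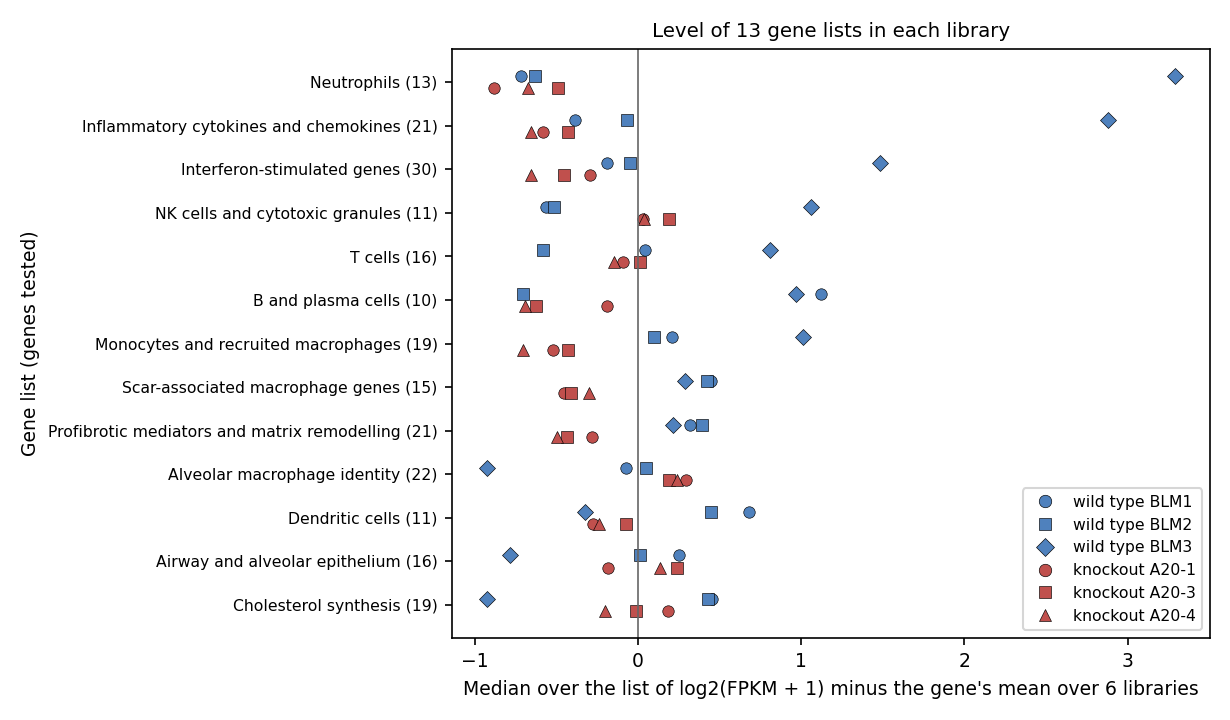
Median over each of 13 gene lists of log2(FPKM + 1) minus the gene's mean over the 6 libraries, for each library labelled wild type (blue) or knockout (red). BLM3 lies at 3.29 for neutrophil genes and 2.88 for inflammatory cytokines and chemokines, while the scar-associated list is negative in each of the 3 knockout libraries and positive in each of the 3 wild-type libraries.

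The 14 named rises ran from 0.98 to 2.25 on the log2 scale. Tppp, a tubulin polymerization factor, went from an FPKM of 0.371 ± 0.233 in wild type to 5.55 ± 1.31 in the knockout libraries (SD, n = 3 each), a log2 difference of 2.25 ± 0.20 (SE, limma adjusted p = 0.0130). Gpx1, glutathione peroxidase, was the most abundant of them, at 65.2 ± 17.7 and 254.3 ± 29.96 FPKM (log2 difference 1.98 ± 0.22, SE, adjusted p = 0.0240). The potassium channel Kcna3 rose from 18.6 ± 5.36 to 51.3 ± 7.87 FPKM, Fpr1 from 61.4 ± 17.5 to 149.1 ± 3.37, the amino acid transporter Slc7a5 from 8.63 ± 1.65 to 20.6 ± 2.47, and the scaffold gene Ahnak from 64.3 ± 4.74 to 127.6 ± 11.2. The lymphocyte genes Klrc1, an inhibitory receptor of natural killer cells, and Fasl, the death ligand, rose by log2 differences of 1.32 ± 0.16 and 1.03 ± 0.15 (SE). The natural killer cell list, which holds neither, had a median of 0.12 (camera adjusted p = 0.463), and without BLM3 0.43 with 11 of 11 members above 0 (camera adjusted p = 0.00455, adjusted p = 0.322 with an estimated correlation, fry adjusted p = 0.0384). Ppp2r2c, Rfx2, Fam102b, Tmub2, the cell cycle kinase Cdk6 and the insulin receptor substrate Irs2 made up the rest, with log2 differences from 0.98 for Irs2 to 1.34 for Ppp2r2c. With the GC and length trend removed, Ahnak, Cdk6, Irs2 and Kcna3 were not called (limma adjusted p = 0.103, 0.0859, 0.0655 and 0.0521). Other calls ended for Kcna3 and Fpr1 with median-ratio scaling (0.0526 and 0.0535), for Kcna3 with quantile normalization (0.0541) and for Ppp2r2c with a pseudocount of 0.1 or 5 (0.0543 and 0.0551).

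The CEBP family of transcription factors, which includes regulators of Arg1, had a median of 0.60 over 6 genes (camera adjusted p = 0.0194, adjusted p = 0.570 with an estimated correlation), with 0 genes called over all genes and 2 rises adjusted over the list alone. Cebpg had 17.6 ± 2.84 FPKM in wild type and 32.7 ± 5.60 in the knockout libraries (SD, n = 3, limma adjusted p = 0.0748), Cebpd 7.24 ± 1.10 and 11.8 ± 1.69 (adjusted p = 0.0991), and Cebpb 278 ± 54.5 and 437 ± 109.9 (adjusted p = 0.202). Of 19 cell death and inflammasome genes, 1 fell over all genes and 2 adjusted over the list alone. This was Pycard, the inflammasome adaptor, from 23.7 ± 2.31 to 13.9 ± 1.11 FPKM, whose call ended with a pseudocount of 0.1 or 5, under TPM, median-ratio or quantile scaling and without a trend (limma adjusted p 0.0502 to 0.0530), and the list as a whole was not called (median -0.03, camera adjusted p = 0.278, or 0.11 with array weights, adjusted p = 0.962). The sensor Aim2 had 21.9 and 11.2 FPKM (limma adjusted p = 0.0889) and the necroptosis effector Mlkl 10.2 and 7.25 (adjusted p = 0.142).

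**Figure D3:**
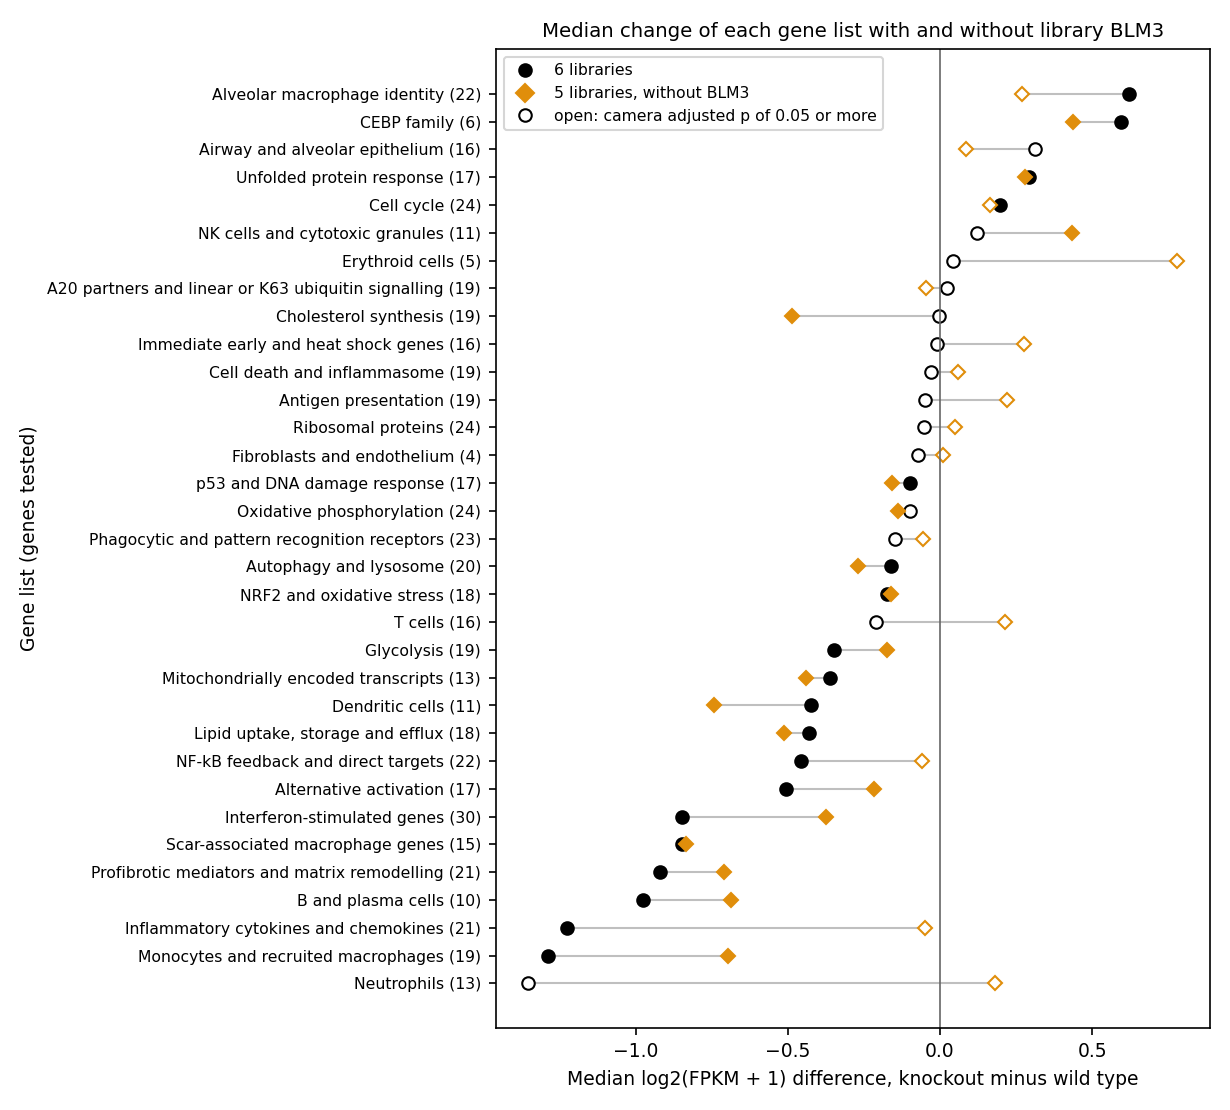
Median log2(FPKM + 1) difference, knockout minus wild type, of 33 gene lists with 6 libraries (black circles) and without BLM3 (orange diamonds); filled symbols have a camera adjusted p under 0.05 at the preset correlation of 0.01. The scar-associated list lies at -0.85 and -0.84, while the cytokine list moves from -1.23 to -0.05 when BLM3 is left out.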

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

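The removal of a GC and length trend was chosen after seeing the data, and the cause of the changes given here was not tested unless stated. The count of rises, 27, and of falls, 91, became 17 and 58 with a minimum mean FPKM of 5, which tests fewer genes, 13 and 59 with a doubling or halving required, 193 and 253 at an adjusted p under 0.1, and 942 and 992 with array weights, which set BLM1 at 6.09 and BLM3 at 0.229. TPM gave 49 rises. With the GC and length trend removed, 14 of the 27 rises and 76 of the 91 falls stayed called. Leaving out each library gave 0 to 144 rises and 0 to 267 falls. Of 40 called genes taken by the rule for named genes and 19 called lists, 0 changed direction under any alternative. For the genes this had to follow with a library left out or another pseudocount, since their values did not overlap between the groups. In the 11 settings with all libraries, where they were tested, at most 6 of the genes lost their call, and at most 5 of the lists (with array weights) in the 10 of them that camera allows, since it has no robust form; leaving out one library cost 40 genes their call without A20-3, 38 without BLM1, 29 without A20-4, 25 without A20-1, 14 without BLM2 and 0 without BLM3, and 2 to 6 lists. Tnfaip3 kept its sign in the 11 settings (0.22 to 0.85, adjusted p 0.133 to 0.830) and ran from -0.141 to 1.27 with a library left out. Directions turned for these results, none of them called: Tgfb1 with array weights (-0.000258), with array weights also the camera tests of neutrophils (-0.01), epithelium (-0.069), erythroid cells (0.206), cell death (0.107), heat shock (0.223) and ribosomal proteins (0.07), the camera test of the epithelial list under TPM (0.379), of fibroblasts and endothelium (0.119) and erythroid cells (0.042) without a filter, of erythroid cells by median ratio (0.03) and of ribosomal proteins under quantile normalization (0.041). With the GC trend removed it turned for erythroid cells (0.179), oxidative phosphorylation (0.011), heat shock (-0.016) and ribosomal proteins (0.022). With a library left out, values of results that turned ran from -0.0125 to 0.359 for Chil3, -0.0255 to 0.11 for Tgfb1, -0.638 to 1.92 for Il1b and -1.81 to 0.0385 for Nos2. List medians ran from -0.074 to 0.048 for A20 partners, -2.031 to 0.179 for neutrophils, -0.532 to 0.214 for T cells, 0.081 to 0.581 for epithelium, -0.165 to 0.01 for fibroblasts and endothelium, -0.958 to 1.014 for erythroid cells, -0.155 to 0.219 for antigen presentation, -0.487 to 0.261 for cholesterol synthesis, -0.309 to 0.275 for heat shock and -0.161 to 0.048 for ribosomal proteins. Scalings moved the median of all genes from 0.021 to at most 0.091. No paired analysis was possible because the table's columns do not carry the titles' replicate numbers. Depth is unknown, so the precision of low values is not known.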

Other observations

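Several lists not described above also moved relative to other genes, and none of their calls held with an estimated correlation. Stress lists went in different directions. The unfolded protein response had a median of 0.29 over 17 genes (camera adjusted p = 0.00899, adjusted p = 0.626 with an estimated correlation; 8 rises and 1 fall adjusted over the list alone; median 0.19 without BLM1, 0.0427), with 35.96 ± 7.14 FPKM of the degradation factor Herpud1 in the knockout and 19.4 ± 0.162 in the wild-type libraries (SD, n = 3, limma adjusted p = 0.0635). Dnajb9, a chaperone, had 33.6 and 24.0 FPKM (adjusted p = 0.104), while the stress factor Atf3 had 20.1 ± 5.32 and 59.1 ± 18.4 (adjusted p = 0.0718). NRF2 and oxidative stress genes had a median of -0.17 (camera adjusted p = 0.0117, adjusted p = 0.460 with an estimated correlation; 2 falls adjusted over the list alone), not called with quantile normalization (0.0677). Srxn1, Nqo1 and Prdx1 led that list, with log2 differences of -0.82, -0.86 and -0.55, and Srxn1 passed without BLM3 (limma adjusted p = 0.0436). Gpx1, which rose, is not on that list. Glycolysis genes had a median of -0.35 (camera adjusted p = 0.00299, adjusted p = 0.626 with an estimated correlation; 2 falls adjusted over the list alone), or -0.17 without BLM3 (camera adjusted p = 0.0105, adjusted p = 0.377 with an estimated correlation), which lay 0.46 above BLM1 and BLM2. Pgam1 and Slc2a1 had log2 differences of -0.62 and -0.92 and passed without BLM3 (limma adjusted p = 0.0363 and 0.0352), and Pfkl had -0.63 (adjusted p = 0.128).

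Dendritic cell genes had a median of -0.42 over 11 genes (camera adjusted p = 0.0151, adjusted p = 0.685 with an estimated correlation), not called without BLM1 (median -0.19, adjusted p = 0.0961) or BLM2 (median -0.27, 0.119) or with a minimum mean FPKM of 5 (0.318). Without BLM3 the median was -0.74 (camera adjusted p = 1.76e-07, adjusted p = 0.322 with an estimated correlation). Kmo, Ccr7 and Xcr1 led it, at 1.18, 26.3 and 0.623 FPKM in the knockout and 2.81, 43.7 and 2.35 in the wild-type libraries (limma adjusted p of 0.109, 0.175 and 0.193), and Xcr1 passed without BLM3 (-1.36, adjusted p = 0.0236). B and plasma cell genes had a median of -0.98 (camera adjusted p = 0.00650, adjusted p = 0.626 with an estimated correlation), or -0.64 without BLM1 (0.0390) and -1.63 without BLM2 (1.04e-08). They were high in BLM1 and BLM3 and not in BLM2, as Blk shows with 16.4, 27.2 and 5.64 FPKM in that order and 3.37 ± 1.29 (SD, n = 3) in the knockout libraries. Cd79b had 26.4, 22.8 and 2.92 FPKM in these libraries, and Fcer2a 5.84, 3.58 and 0.493. Genes of antigen presentation had a median of -0.05 but a mean of 0.13 and were not called (camera adjusted p = 0.471; 2 rises adjusted over the list alone). Their class II members Cd74 and H2-Ab1 had 1754 ± 136 and 807.9 ± 82.2 FPKM in the knockout against 974 ± 206 and 499 ± 94.0 in the wild-type libraries (limma adjusted p of 0.0829 and 0.104), and H2-Eb1 had 898 and 605 (adjusted p = 0.121). Immediate early and heat shock genes were not called (median -0.01, mean 0.02, camera adjusted p = 0.836), yet Hsph1 was at 29.4 and 30.1 FPKM in A20-3 and A20-4, 8.68 in A20-1 and at most 5.41 in the wild-type libraries, and Dnajb1 at 40.5, 38.9, 13.3 and at most 11.9.

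Of the remaining lists, mitochondrially encoded transcripts had a median of -0.36 (camera adjusted p = 0.01004), lost without A20-4 (adjusted p = 0.314), which held 4.0% of its FPKM in them against 6.12% to 7.68% elsewhere, without BLM2 (0.119) and with the GC and length trend removed (0.379). Cell cycle genes had 0.20 (adjusted p = 0.0151), lost without BLM1 (0.238) or BLM3 (0.155), with 0.39 without BLM2 (2.71e-08). Autophagy and lysosome genes had -0.16 (adjusted p = 0.0261), lost without A20-3 (0.0765), BLM1 (0.0575) or BLM2 (0.137), under TPM (0.0514) and with quantile normalization (0.0777). The p53 list had -0.10 (adjusted p = 0.0470), lost without A20-1 (0.226), A20-4 (0.0706) or BLM2 (0.129), with a pseudocount of 5 (0.0538), with no filter (0.0661) and with the GC and length trend removed (0.0527). Medians that moved by over 1.5 times while the call stayed were -0.56 for mitochondrial transcripts without A20-3, -0.27 for autophagy without BLM3, and -0.25, -0.28 and -0.16 for p53 without A20-3, BLM1 and BLM3. Others were -0.021 for p53 under TPM (camera adjusted p = 0.0354) and, for the cell cycle, 0.337 with array weights (0.000221) and 0.12 with a pseudocount of 5 (0.0183). The adjusted p with an estimated correlation was 0.728, 0.806, 0.570 and 0.626 for the mitochondrial, cell cycle, autophagy and p53 lists. Not called were T cells (-0.21, adjusted p = 0.304, called without BLM2 at 0.00234 with a median of -0.53, adjusted p = 0.691 with an estimated correlation), natural killer cells (0.12, 0.463, called without BLM3 at 0.00455, adjusted p = 0.322 with an estimated correlation), epithelium (0.31, 0.721), fibroblasts and endothelium (-0.07, 0.845), erythroid cells (0.04 with a downward test, 0.952), ribosomal proteins (-0.05, 0.161, called without A20-3 at 0.0179 and BLM1 at 0.00944 with medians of -0.135 and -0.161, adjusted p = 0.804 and 0.731 with an estimated correlation), oxidative phosphorylation (-0.10, 0.177, called without BLM3 at 0.0277, adjusted p = 0.679 with an estimated correlation) and cholesterol synthesis (-0.00 median, 0.01 mean, 0.836), which without BLM3 had -0.49 (1.76e-07, adjusted p = 0.541 with an estimated correlation). With array weights, the natural killer (0.0426), antigen presentation (0.0323) and cholesterol (0.000767) lists were called, and the glycolysis (0.0696) and p53 (0.193) lists were not. No list call held with an estimated correlation under any setting in which camera was run. Over all genes tested with 6 libraries, limma called 0 members of the lists from the unfolded protein response to cholesterol synthesis. Adjusted over the list alone, 1 natural killer gene rose, 1 epithelial gene fell, 1 heat shock or immediate early gene rose and 1 fell, and 0 changed in the lists with no count given. Without BLM3, limma called 4 falls in the dendritic cell list, 2 falls each in the glycolysis, epithelial, p53 and cholesterol lists, 1 fall in the NRF2 list, 2 rises in the T cell list and 1 in the natural killer list.

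Of the tests that follow, those on other scalings, GC content and other splits of the libraries were set out before their results were seen, and those on recruited macrophages, on BLM3 and on Tnfaip3 were chosen only after. The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 118 genes and the highest of the others 0, so that 1 split gave as many.

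Most of the 91 falls in the libraries labelled knockout stayed called under other scalings. Under TPM, median-ratio and quantile scaling at least 69 of them stayed called, and 76 did with the trend on GC content and length removed, which argues against the authors' scaling or a GC or length bias as the whole cause of it. A smaller share of recruited macrophages may contribute. Without BLM3 the recruited list had a median of -0.697 (limma's fry, adjusted p = 0.0384, and camera adjusted p = 0.342 with an estimated correlation). It had 1 rise and 4 falls over all genes, and 13 members below and 6 above 0. Its falls include C1qa, C1qb and C1qc, which are among the 91 falls in question, so they are no separate support. The dendritic cell list, of another cell type, had -0.74 (limma's fry, adjusted p = 0.0345, and camera adjusted p = 0.322 with an estimated correlation, with 4 falls). A smaller share of recruited macrophages cannot be told apart from a change within the cells, because bulk values do not separate cell types. The alveolar macrophage list without BLM3 had a median of 0.27 with 14 members above and 8 below 0 (limma's fry, adjusted p = 0.309). The A20 deletion itself stays open and untested, given the level of Tnfaip3.

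Library BLM3 stands apart from BLM1 and BLM2. RNA from neutrophils is a candidate explanation for part of it: 12 of 14 listed neutrophil genes were over 2-fold above both, including S100a9 at 1535 FPKM against 24.8 and 24.8, S100a8 at 861 and Csf3r at 184.5 against 9.37 and 10.96. The exceptions were Mmp8 and Fpr1, and 8 of the 14 had an FPKM of at least 1 in every knockout library. The rise in BLM3 was not confined to neutrophil genes. Medians against BLM1 and BLM2 were 2.21 for erythroid, 1.64 for natural killer, 1.16 for T cell and 0.93 for recruited macrophage genes. They were 0.80 for B and plasma cell genes, 0.25 for fibroblasts and endothelium, and -0.83 for dendritic cell genes. A lower share of alveolar macrophages alone would raise all other cell types alike. The other lists' medians in BLM3 instead spanned 4.96 log2 units, from 4.005 for neutrophils to -0.95 for epithelium. This speaks only against a lower share with the other cell types in fixed proportion. The pseudocount also makes an equal rise look smaller in genes of low FPKM. The alveolar macrophage list itself had a median of -0.985 there, so a lower share beside neutrophil RNA stays open. A stronger inflammatory response of the macrophages in that library stays open and was not tested.

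Tnfaip3 showed no fall in the libraries labelled knockout. Leaving out BLM3, the highest wild-type value, could only raise the difference, which became 1.275 (SE 0.312), so this decides nothing. More T cells could raise Tnfaip3, but the T cell list then had a median of 0.214 and an upper quartile of 0.49, below the Tnfaip3 change. This speaks only against T cells as the source of the whole change, and cannot tell whether lymphocytes masked a fall. Without BLM3 the natural killer list had a median of 0.434 with 11 members above 0 and 0 below. The B and plasma cell list had -0.687 with 0 above 0 and 10 below. Their part in the Tnfaip3 level was not tested. Single libraries exchanged between the groups would leave a knockout library closer to a wild-type one, and the lowest correlation between knockout libraries was 0.9769, above the highest across groups, 0.969. The wild-type libraries did not meet the same rule. BLM3 correlated with BLM1 and BLM2 at 0.9251 and 0.9134, below the 0.969 of BLM2 with A20-1. It correlated with the knockout libraries at 0.8858 to 0.8997. These correlations thus speak to the knockout libraries only and do not settle the place of BLM3. No batch entered the comparison, and libraries of a group that were handled together could also correlate more closely. Group and handling therefore cannot be told apart here. An exchange of whole groups, transcripts that keep most exons of a deleted allele and a small share of deleted cells stay open, untested by whole-gene FPKM.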
